A study of Mus musculus with 10 samples.

How the data were processed

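Medulloblastomas and adjacent cerebellar tissue of CAGGS-CreER and R26-SmoM2 mice were measured on Affymetrix 430A and 430B arrays, with 3 tumours and 2 cerebellum samples on each chip. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made by the Affymetrix procedure. The values are intensity on a linear scale as deposited by the authors, 1 value per probe set and array. The software, the scaling and the background treatment behind them are not given in the sources used here. Between 298 and 477 probe sets per array sit at exactly 1 and at most 3 lie below, so low values appear to have been set to 1. The number of arrays limits the precision, and no measure of detection was used.

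Groups and replicate numbers came from the sample titles, and no column of the tables was left unmapped. Intensities were transformed to log2(value + 16), so a fold change is on that scale and understates the change of low probe sets. Array medians on this scale lay within 0.0729 log2 units on 430A and 0.0544 on 430B, under the limit of 0.5 set for further normalization, so none was applied. The 25% of probe sets with the lowest mean were left out, which left 16969 and 16883 probe sets. Each chip was fitted on its own with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend and two-sided tests. Benjamini-Hochberg adjustment ran over the tested probe sets of a chip, and a call needs an adjusted p below 0.05.

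Gene names came from the platform annotation through Entrez identifiers. On 430A, 20380 of 22626 probe sets name 1 gene, 691 name several and 1555 are not listed, and on 430B these are 14661, 245 and 7605 of 22511. Of the probe sets with 1 gene, 20351 and 14486 were found in the mouse reference gene table of the GRCm38.p6 assembly, and no symbol had to be replaced. The arrays name no genome build, so no coordinates are given and the table served for names and chromosomes. Each gene was represented by 1 probe set that names no other gene. The 430A chip came before 430B, then suffixes other than _s_at and _x_at, then the highest mean.

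The gene lists, 47 in all, were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. A list with at least 4 measured genes was tested with limma's camera at a preset correlation of 0.01, adjusted over lists, on 5 columns that join the chips by tissue and replicate number. The text names all measured Hedgehog target genes with Smo, the 10 largest rises and the 10 largest falls past the test with groups that do not overlap, and up to 4 genes per list past the test by absolute log2 fold change. Where fewer than 2 genes of a list passed, the 2 with the smallest p are given as values. The tables hold no control probe sets, so the planned check of replicate numbers between chips on such probe sets used the 100 probe sets that both chips hold. This replacement was chosen after the data were seen. Lists share genes, such as Sfrp1, Cdkn1a, Pdgfra and Gad1.

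Alternatives changed 1 choice at a time. They were pseudocounts of 1 and 64, quantile normalization, equal array medians, no filter or a filter of 50%, no trend in eBayes, the replicate number as a block, each replicate number of a tissue left out in turn on both chips, an adjusted p below 0.01, a log2 limit of 1, other choices of probe set, an estimated correlation and genes of 430A only. Another 5 were added after the data were seen, namely scaling 430B on the 100 shared probe sets, joining the tumours of the chips in the order that those probe sets match, leaving out the 430B arrays of tumours 1 and 2, leaving out each tumour of 430A with its match on 430B, and recounting genes of single tumours after quantile normalization. With 1 cerebellum array left, the fit takes the spread from the tumours and assumes that the lone sample varies like them. Fewer arrays also cost power, so a call can end while the fold change hardly moves. Named genes whose call ended in those fits are therefore given by log2 fold change. Without the 430B arrays of tumours 1 and 2 the spread comes from the cerebellum samples and the lone tumour is assumed to vary like those, so only counts and the correlation between chips are given for that fit.

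The fit was tested on simulated data with independent noise for each probe set and array. Changes were planted in 65 to 67 probe sets per size and chip and in the mitosis genes. On 430A, 46.3% of probe sets planted at a log2 fold change of 1 were called, 96.9% at 2 and 98.5% at 3, and 5% of the calls were false. On 430B these were 55.4%, 87.9% and 97.0%, and 2.31% of the calls were false. In the real data 32.2% of probe sets were called on 430A and 17.6% on 430B, and single arrays carry differences shared by many genes. The simulated rates therefore do not carry over to the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.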

Results

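The series compared the transcriptome of medulloblastomas with that of adjacent cerebellar tissue, which the labels call wild type, in mice carrying CAGGS-CreER and R26-SmoM2. Medulloblastoma is a malignant tumour of the cerebellum. SmoM2 is an activated form of Smoothened, the membrane protein that switches on the Hedgehog pathway, and CreER is a recombinase that tamoxifen activates. Tamoxifen was injected at postnatal day 10 at 1 mg per 40 g of body weight. RNA of 3 tumours and 2 cerebellum samples was hybridised to each of 2 Affymetrix chips, 430A and 430B, 10 arrays in all. The labels call the samples of a tissue biological replicates. The deposited intensity had a median between 33.3 and 35.9 on the 430A arrays and between 22.5 and 24.0 on the 430B arrays. Between tumours, log2 values correlated across probe sets with r from 0.960 to 0.981 on 430A. Between a tumour and a cerebellum sample r lay from 0.828 to 0.859, and the 2 cerebellum samples had r = 0.981. The values on 430B were 0.929 to 0.969, 0.794 to 0.817 and 0.967.

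The question put to the data was which genes differ between the tumours and the cerebellum beside them. The tumours carried high levels of Hedgehog target genes, of granule neuron precursor genes and of the genes of DNA replication and mitosis. They carried low levels of the genes of mature granule neurons, Purkinje cells, Bergmann glia and astrocytes, myelin, synapses and energy metabolism. These groups were called by camera at a preset correlation, and none of the calls held with an estimated correlation, where the lowest adjusted p was 0.161. RNA came from pieces of tissue, so the levels do not tell a change within cells from a different mix of cells. The largest rises were in Top2a (4.19 ± 0.43), Cdk1 (4.06 ± 0.32), Rassf4 (4.03 ± 0.33), Mcm6 (4.03 ± 0.32), Mki67 (4.001 ± 0.33), Dcx (3.95 ± 0.41), Sstr2 (3.87 ± 0.28), Sfrp1 (3.84 ± 0.23), Cd24a (3.83 ± 0.33) and Atoh1 (3.79 ± 0.21), given as log2 fold change ± SE of tumour over cerebellum. The cerebellum samples lay apart in several of these, and the fold change moved by over 1.5 times when either was left out, with log2 values without cerebellum 1 and without cerebellum 2 in brackets, in Top2a (5.18 and 3.20), Cdk1 (4.71 and 3.41), Mcm6 (4.66 and 3.40), Mki67 (4.68 and 3.32), Dcx (4.72 and 3.17) and Cd24a (4.53 and 3.12). The largest falls were in Gabra6 (-5.97 ± 0.29), Calb1 (-5.65 ± 0.34), Pvalb (-5.22 ± 0.31), Gng13 (-5.17 ± 0.30), Car8 (-5.11 ± 0.23), Mbp (-4.91 ± 0.40), Pcp2 (-4.81 ± 0.26), Pcp4 (-4.67 ± 0.27), Gad1 (-4.64 ± 0.25) and Slc12a5 (-4.62 ± 0.24). Rassf4 had 3.35, Mcm6 3.40, Dcx 2.37, Sfrp1 2.92, Calb1 -4.68, Car8 -4.04, Mbp -3.66 and Pcp2 -3.12 with the mean over probe sets. Gabra6, the GABA-A receptor subunit of granule neurons, had an intensity of 34.8 ± 18.6 in tumours (SD, n = 3) and 3012 ± 11.2 in cerebellum (SD, n = 2). These 20 genes were picked from those past the test whose tumour values did not overlap the cerebellum values, so neither trait is a result. Their adjusted p in limma lay between 3.74e-07 (Car8) and 2.92e-05 (Dcx).

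In limma, 1575 of 14702 genes were higher and 2358 were lower in medulloblastoma at an adjusted p below 0.05. Of these, 752 and 1236 changed by at least 1 log2 unit, and 41 and 99 at least 8-fold. On 430A, 2231 of 16969 probe sets were higher and 3229 lower. On 430B, 1326 of 16883 were higher and 1649 lower. Groups did not overlap in 52.3% of genes, against 20% by chance for 3 tumours and 2 cerebellum samples. With few samples the counts moved with each one. With the arrays numbered cerebellum 1 left out on both chips the test called 940 genes higher and 1686 lower, and with those numbered cerebellum 2 left out it called 875 and 1432. The 430A counts were 1438 higher without cerebellum 1 and 1275 higher and 2057 lower without cerebellum 2. The 430B counts were 621 and 1020 without cerebellum 1, 531 and 954 without cerebellum 2, and 824 higher without medulloblastoma 2. The p-values measure only the spread between these samples, part of which may be technical. On 430B, higher calls made up 44.6% of calls as deposited and 20.5% (700 higher, 2714 lower) when the arrays were scaled on the 100 probe sets both chips hold. They made up 53.7% without medulloblastoma 3 (2603 higher, 2242 lower) and 50% after quantile normalization, which gave 1977 higher and 2036 lower genes over both chips.

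Smo, the gene whose activated form the mice carry, had 60.9, 81.2 and 59.4 units of intensity in the tumours and 39.3 and 37.3 in the cerebellum samples. Its log2 fold change was 0.60 ± 0.17 (adjusted p = 0.0198), and a second probe set gave 1.32 ± 0.19 (adjusted p = 2.5e-04). The sources used here do not say whether these probe sets detect the SmoM2 transcript, so they do not check the labels. The log2 fold change of Smo was 0.63 without cerebellum 1 and 0.58 without cerebellum 2, near that with all samples, though neither fit called it. Of the 7 measured Hedgehog target genes, 5 rose and none fell, and the same count held adjusted over the list alone. Sfrp1, a secreted WNT modulator, changed by 3.84 ± 0.23, and Ccnd2 and Ccnd1, the D cyclins that drive cells into S phase, by 3.60 ± 0.46 and 2.64 ± 0.20. Ccnd2 had 4.45 without cerebellum 1 and 2.75 without cerebellum 2. Mycn, a transcription factor of proliferating precursors, changed by 2.87 ± 0.23, and Gli1, the transcriptional effector of the pathway, by 1.45 ± 0.17. Mycn had 1.41 and Sfrp1 2.92 with the mean over probe sets. The camera test of the list gave an adjusted p of 5.6e-06, and adjusted p = 0.169 with an estimated correlation.

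Ptch1, the Hedgehog receptor and a target gene, depended on the probe set. The 430A probe set chosen for it read 1020 ± 136 in tumours (SD, n = 3) and 945 ± 54.6 in cerebellum (SD, n = 2), a log2 fold change of 0.10 ± 0.17 (adjusted p = 0.717). After quantile normalization the same gene gave 0.68 with an adjusted p of 0.0109. The Ptch1 probe set of 430B gave 1.86 ± 0.23 (adjusted p = 3.2e-04), with means of 324 and 77.0. A second 430A probe set gave 0.26 ± 0.15 (adjusted p = 0.232), so 1 of 3 was called. Hhip, a ligand-binding inhibitor of the pathway and also a target, had a log2 fold change of 0.26 ± 0.24 (adjusted p = 0.473), and 0.51 with an adjusted p of 0.0303 without medulloblastoma 2. Of 18 other pathway components, 7 rose and 3 fell, and 7 and 4 did so adjusted over the list alone. Among them Gli2, a transcriptional activator, had 2.37 ± 0.16, Sufu, an inhibitor of the GLI proteins, 1.37 ± 0.22, Gpr161, a ciliary receptor, 1.06 ± 0.13 and Arrb1 -1.41 ± 0.16. Sufu also depended on the probe set, with -0.14 (adjusted p = 0.525) and 0.02 (0.955) from its 2 other probe sets and 0.62 with the mean over probe sets. The camera adjusted p of that list was 0.0902, and it was 0.0115 with no filter on low values, 0.0137 with the lower 50% left out, 0.0395 with the brightest probe set of each gene and 0.0204 with genes of 430A only. Of the pathway components, 4 rose without cerebellum 1 and 1 fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 2 or with no filter on low values.

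**Figure D1:**
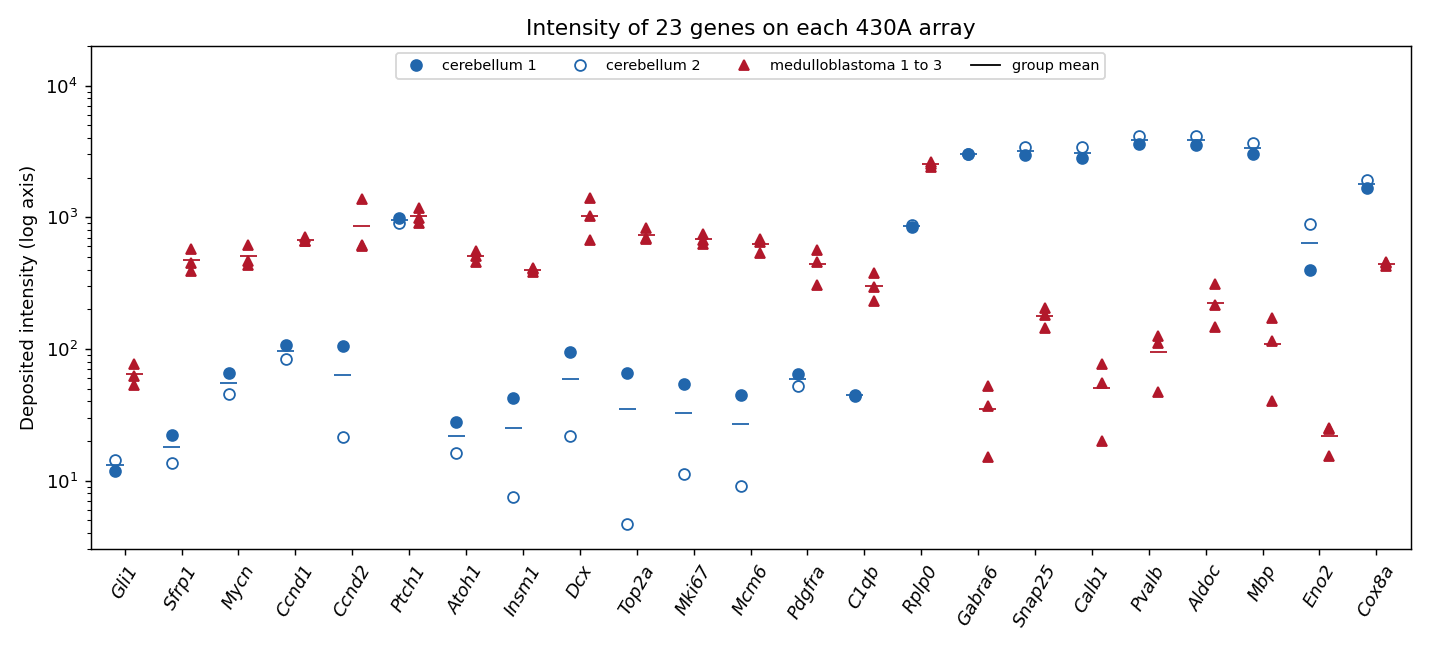
Deposited intensity, on a log axis, of 23 genes on the 5 arrays of the 430A chip, with circles for the 2 cerebellum samples, triangles for the 3 tumours and short lines for group means. Gli1 to Rplp0 lie higher in the tumours except Ptch1, whose values overlap, and Gabra6 to Cox8a lie lower.

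Markers of granule neuron precursors, the dividing cells of the postnatal external granular layer, were high in the tumours. Of 16 measured markers 10 rose and 2 fell, and 12 and 2 did so adjusted over the list alone (camera adjusted p = 1.12e-06, and adjusted p = 0.235 with an estimated correlation). Atoh1, the transcription factor of the granule lineage, changed by 3.79 ± 0.21, Insm1, a factor of dividing neural progenitors, by 3.48 ± 0.32, Sox11 by 3.07 ± 0.32 and Dcx, a microtubule protein of migrating young neurons, by 3.95 ± 0.41. Insm1 had 4.14 without cerebellum 1 and 2.82 without cerebellum 2, and Dcx 4.72 and 3.17. Of 5 orthologues of the human SHH subgroup signature, 2 rose, Sfrp1 and Atoh1, and both did so adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.221 with an estimated correlation). Among 8 orthologues of the human group 3 and group 4 signatures 2 rose and 2 fell, with the same counts over the list alone (camera adjusted p = 0.838, and adjusted p = 0.883 with an estimated correlation). They were Mab21l2 (2.75 ± 0.19), Rbm24 (0.70 ± 0.16), Kcna1 (-2.94 ± 0.22) and Eomes (-1.71 ± 0.14). Only 2 orthologues of the WNT subgroup signature were measured, too few for the list test, with Gad1 at -4.64 ± 0.25 and Tnc at -0.67 ± 0.27 (adjusted p = 0.0907); adjusted over the list alone both were lower. Tnc had an adjusted p of 0.00128 without medulloblastoma 2. Rbm24 had a log2 fold change of 0.61 without cerebellum 1 and 0.79 without cerebellum 2. Its adjusted p was 0.282 with 430B scaled on the shared probe sets. Of the orthologues of groups 3 and 4, 1 rose without cerebellum 1 or cerebellum 2. Of the WNT subgroup orthologues, 2 fell without medulloblastoma 2.

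Mitosis genes had the largest share of higher genes of all lists, followed by those of DNA replication. Of 42 mitosis genes 39 rose, 39 also adjusted over the list alone, and none fell (camera adjusted p = 4.23e-33, and adjusted p = 0.161 with an estimated correlation). They included Top2a (4.19 ± 0.43), Cdk1 (4.06 ± 0.32), Mki67 (4.001 ± 0.33) and Ccna2 (3.67 ± 0.34), which act in chromosome condensation and entry into mitosis or mark dividing cells. Without cerebellum 1 and without cerebellum 2 their log2 fold changes were Top2a (5.18 and 3.20), Cdk1 (4.71 and 3.41), Mki67 (4.68 and 3.32) and Ccna2 (4.39 and 2.95), and those of the helicase gene Mcm6 (4.66 and 3.40). Of 32 genes of DNA replication and S phase 29 rose, or 30 adjusted over the list alone (camera adjusted p = 9.23e-21, and adjusted p = 0.161 with an estimated correlation). Parts of the replicative helicase were among them, Mcm6 (4.03 ± 0.32), Mcm7 (3.12 ± 0.25) and Mcm2 (2.88 ± 0.19), with the ribonucleotide reductase subunit Rrm2 (3.11 ± 0.22). Among the D cyclins and their partners 8 of 10 rose, 8 also adjusted over the list alone (camera adjusted p = 4.49e-06, and adjusted p = 0.161 with an estimated correlation), with E2f2 (2.88 ± 0.19) and Cdk4 (2.79 ± 0.24). Of the D cyclins and partners, 4 rose without cerebellum 2. Genes that restrain the cycle moved up too, 5 of 10 cyclin-dependent kinase inhibitors and RB family genes, with 1 lower, also adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.161 with an estimated correlation). These were led by Cdkn2c (1.53 ± 0.21), Rbl1 (1.26 ± 0.16), Cdkn1a (1.24 ± 0.19) and Rb1 (0.80 ± 0.21). Of the kinase inhibitors and RB family genes, 3 rose without cerebellum 1 and none fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 3. Rb1 had a log2 fold change of 0.82 without cerebellum 1 and 0.77 without cerebellum 2.

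Among chromatin regulators, splicing factors and cytoplasmic ribosomal proteins, more genes rose than fell. Of 26 chromatin regulators 15 rose and 1 fell, 18 and 1 adjusted over the list alone (camera adjusted p = 1.37e-09, and adjusted p = 0.161 with an estimated correlation). They included the architectural proteins Hmgb2 (3.59 ± 0.32) and Hmgb3 (2.76 ± 0.23), the DNA methylation cofactor Uhrf1 (2.94 ± 0.23) and the histone methyltransferase Ezh2 (2.60 ± 0.24). Uhrf1 had 2.21 with the mean over probe sets. Hmgb2 had 4.24 without cerebellum 1 and 2.95 without cerebellum 2. Among 20 splicing factors 9 rose and 1 fell, 10 and 1 adjusted over the list alone (camera adjusted p = 4.65e-05, and adjusted p = 0.169 with an estimated correlation), as with Ptbp1 (2.17 ± 0.22), Snrpf (1.71 ± 0.31), Hnrnpa1 (1.26 ± 0.23) and Lsm2 (1.22 ± 0.16). Of the splicing factors, 5 rose without cerebellum 2 and none fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 3. Of the chromatin regulators, none fell without cerebellum 1, cerebellum 2 or medulloblastoma 1. Of 14 cytoplasmic ribosomal proteins 9 rose, 10 adjusted over the list alone (camera adjusted p = 1.64e-06, and adjusted p = 0.161 with an estimated correlation). Rplp0 had an intensity of 2533 ± 109 in tumours (SD, n = 3) and 853 ± 23.7 in cerebellum (SD, n = 2), a log2 fold change of 1.55 ± 0.14, and Rpl22 (1.60 ± 0.18), Rps6 (1.28 ± 0.21) and Rps4x (1.00 ± 0.16) rose with it. Snrpf had a log2 fold change of 1.65 without cerebellum 1 and 1.77 without cerebellum 2.

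Markers of the mature neurons of the cerebellum fell. Of 16 markers of mature granule neurons 15 fell, 15 also adjusted over the list alone (camera adjusted p = 2.94e-14, and adjusted p = 0.161 with an estimated correlation), led by Gabra6 (-5.97 ± 0.29), Vsnl1 (-4.18 ± 0.20), Snap25 (-4.07 ± 0.20) and Kcnd2 (-4.05 ± 0.20). All 13 measured markers of Purkinje cells, the output neurons of the cerebellar cortex, fell, 13 also adjusted over the list alone (camera adjusted p = 1.09e-13, and adjusted p = 0.175 with an estimated correlation). The largest were in Calb1 (-5.65 ± 0.34), Pvalb (-5.22 ± 0.31), Car8 (-5.11 ± 0.23) and Pcp2 (-4.81 ± 0.26). Of 9 markers of GABAergic interneurons 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00221, and adjusted p = 0.305 with an estimated correlation), among them Gad1, which makes GABA, at -4.64 ± 0.25 and Lgi2 (-2.49 ± 0.16), Kit (-2.13 ± 0.21) and Tfap2b (-2.12 ± 0.23). Tfap2b had -0.85 with no filter on low values. Lgi2 had -1.83 with the mean over probe sets. With genes of 430A only that list had an adjusted p above 0.05, at 0.128. Of the interneuron markers, none rose without cerebellum 1, cerebellum 2, medulloblastoma 2 or medulloblastoma 3.

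Synaptic, channel and calcium signalling genes fell with them. Of 22 synaptic vesicle genes 18 fell and 1 rose, 20 and 1 adjusted over the list alone (camera adjusted p = 2.78e-10, and adjusted p = 0.169 with an estimated correlation), with Snap25 (-4.07 ± 0.20), Vamp1 (-3.18 ± 0.18), Syngr1 (-3.05 ± 0.25) and Napb (-2.93 ± 0.25). The other probe set of Syngr1 gave 0.45 ± 0.20 (adjusted p = 0.106). Syngr1 had -1.30 with the mean over probe sets. Among 27 voltage-gated ion channel genes 17 fell and 1 rose, 20 and 1 adjusted over the list alone (camera adjusted p = 2.78e-10, and adjusted p = 0.161 with an estimated correlation), with Cacnb4 (-4.32 ± 0.19), Scn2a (-4.28 ± 0.19), Kcnd2 (-4.05 ± 0.20) and Scn1a (-3.63 ± 0.17). Scn2a had -3.69 with the mean over probe sets. Of 9 GABA-A receptor subunits 7 fell, 7 also adjusted over the list alone (camera adjusted p = 7.65e-06, and adjusted p = 0.161 with an estimated correlation), and after Gabra6 came Gabrd (-2.78 ± 0.17), Gabrb1 (-2.14 ± 0.17) and Gabra2 (-1.75 ± 0.17). Gabra2 had -1.13 with no filter on low values. Glutamate receptors fell in 8 of 21 cases, 8 also adjusted over the list alone (camera adjusted p = 0.000522, and adjusted p = 0.161 with an estimated correlation), with Gria1 (-2.89 ± 0.21), Grm4 (-2.65 ± 0.27), Grm3 (-2.28 ± 0.20) and Grin2c (-2.15 ± 0.18). Of 20 calcium and calmodulin signalling genes 16 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 4.26e-09, and adjusted p = 0.161 with an estimated correlation). The calcium pumps Atp2b3 (-3.68 ± 0.28), Atp2a2 (-3.32 ± 0.19) and Atp2b2 (-3.08 ± 0.31) and the kinase Camkk2 (-2.82 ± 0.20) had the largest changes. The other probe set of Atp2b3 gave -0.21 ± 0.15 (adjusted p = 0.414). Atp2b3 had -1.94, Atp2a2 -2.27, Atp2b2 -2.28 and Camkk2 -1.56 with the mean over probe sets.

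Glial markers went in different directions. Of 18 markers of Bergmann glia and astrocytes 16 fell, 16 also adjusted over the list alone with 1 higher (camera adjusted p = 6.47e-12, and adjusted p = 0.161 with an estimated correlation), with Aldoc (-4.06 ± 0.26), Gja1 (-3.51 ± 0.24), Sparcl1 (-3.46 ± 0.23) and Slc4a4 (-3.11 ± 0.20). Aldoc had -3.19 and Slc4a4 -1.77 with the mean over probe sets. Of 11 markers of myelinating oligodendrocytes 9 fell, 10 adjusted over the list alone (camera adjusted p = 6.02e-08, and adjusted p = 0.161 with an estimated correlation), with Mbp (-4.91 ± 0.40), Mobp (-4.28 ± 0.22), Ermn (-2.82 ± 0.19) and Ugt8a (-1.75 ± 0.25), genes of the myelin sheath or its lipids. Markers of oligodendrocyte precursors rose in 4 of 9 cases, 5 adjusted over the list alone (camera adjusted p = 0.000608, and adjusted p = 0.175 with an estimated correlation). These were the receptor Pdgfra (2.58 ± 0.26), the transcription factors Olig2 (1.27 ± 0.20) and Olig1 (1.14 ± 0.22) and the matrix protein Vcan (0.97 ± 0.34). Relative to the other tumours, the median of 7 of these markers on 430A was -0.57 in tumour 2 and 0.41 in tumour 3, in single arrays. Markers of microglia and macrophages rose in 10 of 16 cases, 10 also adjusted over the list alone (camera adjusted p = 2.34e-07, and adjusted p = 0.161 with an estimated correlation). The complement subunits C1qb (2.37 ± 0.23), C1qc (2.35 ± 0.21) and C1qa (2.13 ± 0.20) and the signalling adaptor Tyrobp (2.04 ± 0.21) led them. Vcan had a log2 fold change of 1.10 without cerebellum 1 and 0.84 without cerebellum 2. Its adjusted p was 0.163 without medulloblastoma 1, 0.148 without medulloblastoma 3 and 0.056 with a pseudocount of 1. It was 0.0808 with no filter on low values and 0.0548 without the trend in eBayes. Of the Bergmann glia and astrocyte markers, 1 rose without medulloblastoma 3.

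**Figure D2:**
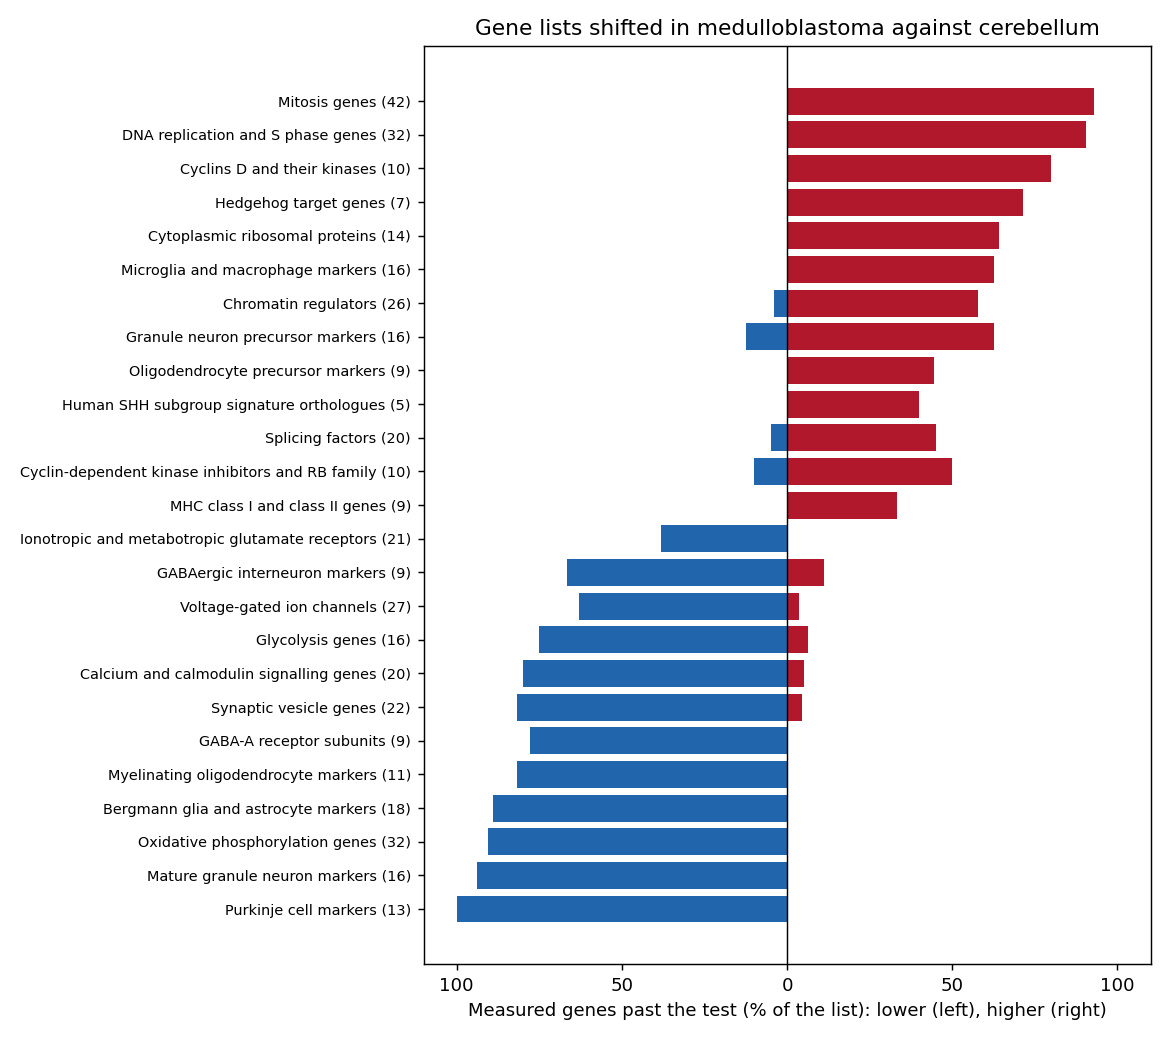
Percent of the measured genes of each list that passed the limma test (adjusted p below 0.05), lower in medulloblastoma to the left and higher to the right, for the 25 lists called by camera with the preset correlation; the number of measured genes follows each name. Mitosis genes reach 92.9% higher and Purkinje cell markers 100% lower; no list was called with an estimated correlation.

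Most genes of the oxidative phosphorylation and glycolysis lists had lower transcript levels in the tumours, as measured over whole tissue and not per cell. Of 32 genes of oxidative phosphorylation 29 fell, 29 also adjusted over the list alone (camera adjusted p = 2.63e-12, and adjusted p = 0.169 with an estimated correlation), with Cox8a (-1.98 ± 0.17), Cox6a1 (-1.95 ± 0.17), Atp5b (-1.73 ± 0.18) and Cox5b (-1.71 ± 0.17). Of 16 glycolysis genes 12 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 9.42e-07, and adjusted p = 0.218 with an estimated correlation). Aldoc and Eno2 had -4.06 ± 0.26 and -4.03 ± 0.30, and Aldoa and Pfkm had -2.87 ± 0.20 and -2.58 ± 0.26. Of 12 hypoxia response genes 4 fell, 5 adjusted over the list alone, and none rose (camera adjusted p = 0.0836, and adjusted p = 0.242 with an estimated correlation), with Bnip3 (-1.94 ± 0.21), Slc2a1 (-1.45 ± 0.21), Vegfa (-1.02 ± 0.14) and Car9 (-0.70 ± 0.16). That list passed the camera test with a pseudocount of 64 (adjusted p = 0.0147), with no filter on low values (0.016), with the mean over probe sets (0.00722) and with 430B scaled on the shared probe sets (0.0408). Car9 had a log2 fold change of -0.61 without cerebellum 1. Of the hypoxia response genes, 2 fell with the lowest 50% left out. No named gene still tested under that filter lost its call, so the others had dropped out of the test.

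Of 9 MHC class I and class II genes 3 rose, 3 also adjusted over the list alone (camera adjusted p = 0.0429, and adjusted p = 0.515 with an estimated correlation), namely the class II genes H2-Aa (1.72 ± 0.18) and H2-Eb1 (1.31 ± 0.24) and the invariant chain Cd74 (1.49 ± 0.44). The list had an adjusted p of 0.123 without cerebellum 1, 0.0947 without the arrays numbered medulloblastoma 2, 0.0553 with a pseudocount of 64 and 0.0618 with no filter on low values. It was 0.126 without tumour 2 of 430A and its match on 430B. Cd74 had a log2 fold change of 1.34 without cerebellum 1, 1.65 without cerebellum 2 and 0.89 without medulloblastoma 2. Among 13 interferon-stimulated genes 1 rose and 1 fell, also adjusted over the list alone, Psmb8 (0.54 ± 0.14) and Ifit3 (-0.60 ± 0.17) (camera adjusted p = 0.74, and adjusted p = 0.883 with an estimated correlation). Of 10 immediate early genes 3 fell, 3 also adjusted over the list alone, Fos (-2.25 ± 0.22), Egr1 (-1.45 ± 0.19) and Dusp1 (-1.17 ± 0.28) (camera adjusted p = 0.225, and adjusted p = 0.515 with an estimated correlation). In the heat shock list, which also holds the stress response gene Ddit3, 4 of 11 genes fell. They were Hsp90aa1 (-1.08 ± 0.14), Hspa1b (-1.06 ± 0.21), Hspa8 (-0.83 ± 0.16) and Ddit3 (-0.62 ± 0.17). Adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.218, and adjusted p = 0.699 with an estimated correlation). Ddit3 and Ifit3 had log2 fold changes of -0.61 and -0.56 without cerebellum 1. Ddit3, Dusp1, Ifit3 and Psmb8 had log2 fold changes of -0.62, -1.004, -0.65 and 0.50 without cerebellum 2. Ifit3 had an adjusted p of 0.0596 without medulloblastoma 1. Ddit3 and Ifit3 had adjusted p values of 0.0652 and 0.056 without medulloblastoma 3. Hspa8 had an adjusted p of 0.0734 after quantile normalization. Of the interferon-stimulated genes, none rose without cerebellum 2 and none fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 3. Of the immediate early genes, 1 rose without medulloblastoma 1. Of the heat shock genes, 1 rose without medulloblastoma 2 and 2 rose after quantile normalization. Of the MHC genes, 6 rose with the mean over probe sets.

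Signalling and survival lists held single changes. Of 15 Notch pathway genes 3 rose, 3 also adjusted over the list alone, Hey1 (1.47 ± 0.20), Rbpj (0.64 ± 0.19) and Nrarp (0.51 ± 0.16) (camera adjusted p = 0.218, and adjusted p = 0.644 with an estimated correlation). Of the Notch pathway genes, 1 rose without cerebellum 1 or cerebellum 2 and 2 fell without medulloblastoma 2. Of 8 WNT feedback targets 2 rose, 2 also adjusted over the list alone, Apcdd1 (1.27 ± 0.16) and Nkd1 (1.18 ± 0.15) (camera adjusted p = 0.121, and adjusted p = 0.521 with an estimated correlation). Apcdd1 was also called by its other 430A probe sets (0.84 and 1.19), but not by those of 430B (0.31 and 0.37). Among 12 insulin-like growth factor genes 4 rose and 2 fell, also adjusted over the list alone, with Irs1 (2.11 ± 0.21), Igf1 (1.11 ± 0.18), Igfbp2 (0.78 ± 0.19) and Igf2r (-1.34 ± 0.18) (camera adjusted p = 0.371, and adjusted p = 0.732 with an estimated correlation). Of the insulin-like growth factor genes, 2 rose without cerebellum 1 and 1 fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 3. Of 14 p53 target genes 2 rose and 2 fell, also adjusted over the list alone, Trp53inp1 (1.47 ± 0.22), Cdkn1a (1.24 ± 0.19), Sesn1 (-0.99 ± 0.22) and Zmat3 (-0.80 ± 0.25) (camera adjusted p = 0.384, and adjusted p = 0.515 with an estimated correlation). In the BCL2 family 3 of 13 genes rose and 2 fell, also adjusted over the list alone, with Bok (2.53 ± 0.23), Bcl2l11 (1.32 ± 0.26), Bcl2l2 (-1.21 ± 0.17) and Bcl2l1 (-0.82 ± 0.19) (camera adjusted p = 0.149, and adjusted p = 0.305 with an estimated correlation). Bcl2l11 had 0.63 and Bcl2l2 -0.32 with the mean over probe sets. Bcl2l1 had -0.21 (limma adjusted p = 0.307) and -0.22 (0.399) from its 2 other probe sets. Of 15 sterol biosynthesis genes 1 rose and 2 fell, also adjusted over the list alone, Srebf1 (2.27 ± 0.30), Sc5d (-0.90 ± 0.27) and Msmo1 (-0.71 ± 0.21) (camera adjusted p = 0.451, and adjusted p = 0.732 with an estimated correlation). Igfbp2, Msmo1, Nrarp, Rbpj and Zmat3 had log2 fold changes of 0.59, -0.76, 0.44, 0.73 and -0.76 without cerebellum 1. Bcl2l1, Msmo1, Nrarp, Rbpj, Sc5d and Zmat3 had log2 fold changes of -0.75, -0.66, 0.59, 0.54, -0.57 and -0.84 without cerebellum 2. Nrarp and Zmat3 had adjusted p values of 0.0756 and 0.105 without medulloblastoma 1. Nrarp and Zmat3 had adjusted p values of 0.0677 and 0.0505 without medulloblastoma 3. Zmat3 had an adjusted p of 0.0828 after quantile normalization. Bcl2l2 had an adjusted p of 0.0776 with the mean over probe sets. Of the p53 target genes, 1 fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 3. Of the BCL2 family, 1 fell without cerebellum 2. Of the sterol biosynthesis genes, 3 rose after quantile normalization, with array medians set equal or with the lowest 50% left out, 4 rose without medulloblastoma 2, none fell without cerebellum 2 and 1 fell without cerebellum 1.

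Lists of tissue and cells that a dissected piece could also hold gave no camera call. Of 10 meningeal fibroblast markers 2 rose and 1 fell, also adjusted over the list alone, Pdgfra, Col3a1 (1.34 ± 0.19) and Ogn (-1.96 ± 0.14) (camera adjusted p = 0.73, and adjusted p = 0.883 with an estimated correlation). Of 5 choroid plexus markers 1 rose and 2 fell, also adjusted over the list alone, Otx2 (1.82 ± 0.19), Ttr (-0.83 ± 0.19) and Kcnj13 (-0.44 ± 0.13) (camera adjusted p = 0.883, and adjusted p = 0.892 with an estimated correlation). Ttr had -1.46 with the mean over probe sets and -2.08 with the brightest probe set. Among 8 forebrain markers 2 rose and 1 fell, also adjusted over the list alone, Lhx2 (1.98 ± 0.23), Neurod6 (1.60 ± 0.23) and Ppp1r1b (-0.87 ± 0.21) (camera adjusted p = 0.387, and adjusted p = 0.521 with an estimated correlation). None of 9 brainstem and midbrain markers passed, over all genes or over the list alone, with Hoxb2 at -0.33 ± 0.15 (adjusted p = 0.119) and Ddc at -0.20 ± 0.15 (adjusted p = 0.437), and the camera adjusted p was 0.863. Of 11 neural stem cell and radial glia markers 1 rose and 1 fell, also adjusted over the list alone, Sox9 (0.65 ± 0.20) and Sox2 (-0.92 ± 0.21) (camera adjusted p = 0.591, and adjusted p = 0.866 with an estimated correlation). Of 12 endothelial and pericyte markers 1 fell and none did so adjusted over the list alone, Flt1 (-0.46 ± 0.14), with Cldn5 at 0.21 ± 0.15 (adjusted p = 0.359; camera adjusted p = 0.976). Of 7 T and B cell markers 1 fell, 1 also adjusted over the list alone, Thy1 (-3.26 ± 0.24), which neurons express as well, and Cd79a had 0.22 ± 0.14 (adjusted p = 0.282; camera adjusted p = 0.863). The median of that list was 0.01 and its mean -0.43. For red blood cells 3 genes were measured, too few for the list test, and 1 fell, also adjusted over the list alone, Hbb-b2 (-1.26 ± 0.30), with Alas2 at -0.13 ± 0.15 (adjusted p = 0.586). None of 4 sex-linked transcripts passed, over all genes or over the list alone, with Eif2s3y at 0.62 ± 0.27 (adjusted p = 0.106) and Xist at 0.18 ± 0.17 (adjusted p = 0.484; camera adjusted p = 0.46). Xist and Eif2s3y mark opposite sexes, so the camera test of their list cannot tell whether the groups differ in sex. Eif2s3y had an adjusted p of 0.00139 without medulloblastoma 2. Sox9 had a log2 fold change of 0.54 without cerebellum 1. Hbb-b2, Ppp1r1b, Sox2, Sox9 and Ttr had log2 fold changes of -1.05, -0.46, -0.88, 0.76 and -0.51 without cerebellum 2. Sox9 had an adjusted p of 0.0728 without medulloblastoma 3. Flt1 had a log2 fold change of -0.52 without cerebellum 1 and -0.41 without cerebellum 2. Its adjusted p was 0.0636 without medulloblastoma 1, 0.0638 without medulloblastoma 3 and 0.052 with array medians set equal. Kcnj13 had a log2 fold change of -0.43 without cerebellum 1 and -0.45 without cerebellum 2. Its adjusted p was 0.114 without medulloblastoma 1, 0.0847 without medulloblastoma 2 and 0.056 with a pseudocount of 1. It was 0.0644 after quantile normalization, 0.0647 with array medians set equal, 0.0866 with no filter on low values and 0.0686 without the trend in eBayes. Of the meningeal markers, 2 fell without medulloblastoma 2. Of the choroid plexus markers, none fell without cerebellum 2 and 1 fell without cerebellum 1, medulloblastoma 1 or medulloblastoma 2. Of the forebrain markers, none fell without cerebellum 2. Of the neural stem cell markers, none rose without cerebellum 1, cerebellum 2 or medulloblastoma 3, 2 rose without medulloblastoma 1, 3 rose without medulloblastoma 2, 4 rose after quantile normalization, none fell without cerebellum 2 and 3 fell without medulloblastoma 2. Of the endothelial and pericyte markers, 1 rose without medulloblastoma 2 and none fell without cerebellum 1, cerebellum 2, medulloblastoma 1 or medulloblastoma 3. Of the red blood cell genes, none fell without cerebellum 2. Of the sex-linked transcripts, 1 rose without medulloblastoma 2.

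Of the 45 lists tested, 25 were called at the preset correlation, 13 higher and 12 lower. None was called with an estimated correlation, where the lowest adjusted p was 0.161 and 13 lists had an unadjusted p below 0.05. The 5 columns leave few residual degrees of freedom. The correlation is estimated from them, and with an estimated correlation camera also takes its p from them. Among called lists the estimates ran from -0.04 for cyclin-dependent kinase inhibitors and the RB family to 0.72 for Purkinje cell markers. Lists with values below the preset one lost their call too, among them myelinating oligodendrocyte markers (-0.03) and glutamate receptors (-0.02), so a high correlation did not end those calls. The unadjusted camera p of the myelinating oligodendrocyte markers went from 1.47e-08 to 0.00952. A lost call is therefore not by itself a sign of correlated genes.

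A further comparison asked whether the 2 chips gave the same changes for genes that both measure with different probe sets. Over 2687 such genes the log2 fold changes of the chips had Pearson r = 0.591 and Spearman rho = 0.475 across genes, which are not independent replicates. Of 882 genes called on 430A and 557 called on 430B, 310 were called on both, 297 in the same direction and 13 in opposite directions. Both chips carry RNA of the same samples, so deviations of single samples can enter both. Across both chips 6790 genes had several probe sets. Of those, 876 had no call by the chosen probe set and a call by another, and 45 had calls in opposite directions. Of 87 named genes called and with several probe sets, 32 had another that was not called and 8 had another of opposite sign. None had another called in the opposite direction.

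The tumour numbers of the labels did not match between chips. Each tumour's deviations from the tumour mean in the 100 shared probe sets were set against those of every tumour on the other chip. Tumour 1 of 430A correlated best with tumour 2 of 430B (r = 0.83), tumour 2 with tumour 3 (r = 0.86) and tumour 3 with tumour 1 (r = 0.73). Pairs of the same number gave 0.22, -0.68 and -0.52. In 270 genes measured by different probe sets the matched order had a mean r of 0.520 and the order of the labels -0.292. The best of the other orders had 0.294 there. The difference between cerebellum 1 and cerebellum 2 correlated between the chips with r = 0.744 in the shared probe sets and 0.513 in the 270 genes. The genes and probe sets were fitted on each chip alone, so with all arrays and no replicate block no gene result depends on the tumour numbers. Leaving out a tumour by its number removes arrays on the 2 chips that did not match. With tumour 2 of 430A and its match on 430B left out, 2333 genes were higher and 2815 lower, against 1799 and 2507 without the arrays numbered 2. The list test joins the chips by number, and 25 lists were called with either order.

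**Figure D3:**
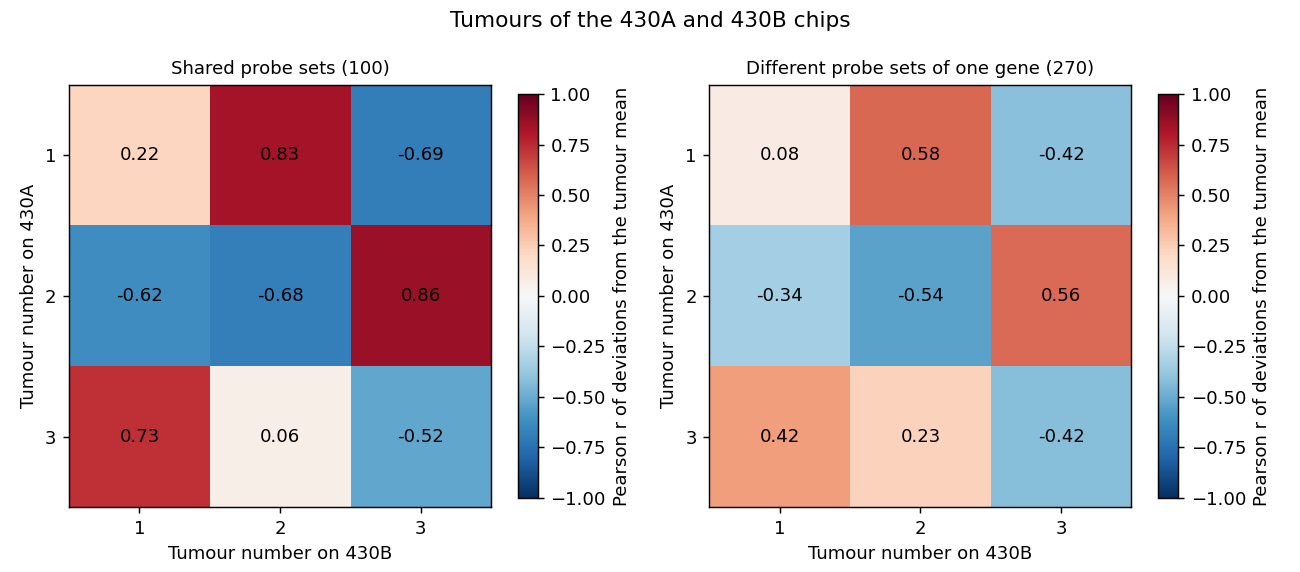
Pearson r, across probe sets, between the deviations of each tumour on 430A (rows) and each tumour on 430B (columns) from the mean of the 3 tumours, for 100 probe sets on both chips (left) and 270 genes with different probe sets on each chip (right). The highest values of each row, 0.83, 0.86 and 0.73 on the left, lie off the diagonal of equal numbers.

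Single tumours were compared with the other tumours chromosome by chromosome. For 120 combinations of chip, tumour and chromosome, the median over genes of the log2 difference from the mean of the other 2 tumours was set against 10000 random gene sets matched on mean expression. It fell outside the central 99% in 22, against 1.2 by chance, and in 13 when genes with a spread of 1 log2 unit or more among tumours were left out. The sizes were small, with the largest at 0.15. On 430B all 20 chromosomes were negative in tumour 3 (-0.14 to -0.03, middle value -0.07) and all 20 positive in tumour 1 (0.04 to 0.15, middle value 0.08), so part of each 430B value lies in the whole array. Chromosome 14 was at -0.15 in tumour 2 of 430A over 347 genes and at -0.14 in tumour 3 of 430B over 270 genes. Chromosome X was at 0.08 in tumour 3 of 430A over 305 genes and at 0.15 in tumour 1 of 430B over 254 genes. In the opposite direction it was at -0.07 in tumour 2 of 430A and at -0.13 in tumour 3 of 430B. These are descriptions of single tumours without a test across animals.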

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

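The scaling of 430B on shared probe sets, the matched order of tumours, the fit without 2 of the 430B arrays and the fits without a matched tumour were chosen after the data were seen. Of 3933 genes called, between 3339 (lowest 50% left out) and 3892 (pseudocount 64) were called in the same direction under the other pseudocounts, normalizations, filters and variance settings. Under the filter of the lowest 50% 3401 were still tested and 3 were called in the opposite direction. Leaving out 1 tumour number on both chips kept between 3126 and 3589 of these genes called. Leaving out the arrays of any 1 replicate number on both chips turned the sign of none. Where the groups of a gene did not overlap this could not happen, so it does not speak for robustness. Higher probe sets on 430A ranged from 1275 to 2806 and lower ones from 2057 to 3710, and on 430B from 531 to 2603 and from 954 to 2242. Genes ranged from 875 to 1799 higher and from 1432 to 2507 lower, called lists from 24 to 25, and r between chips from 0.567 to 0.593. Without each tumour of 430A and its match on 430B, genes ranged from 1197 to 2333 higher and from 1871 to 2815 lower. Quantile normalization gave 2733 higher and 2666 lower probe sets on 430A, 50.6% higher against 40.9% as deposited. The median log2 fold change of all 430A probe sets was -0.05 as deposited and 0.02 after it.

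The labels give tumour and cerebellum samples the same numbers without saying that they share an animal, and 2 numbers are shared. Deviations of same-numbered samples correlated at -0.03 and 0.17 on 430A and at 0.11 and 0.02 on 430B. With the replicate block, 430B had 2822 higher and 2395 lower probe sets (54.1% higher) and r between chips was 0.567. The block leaves tumour 3 no partner, so it drops out of the difference between tissues. As the tumour numbers did not match between the chips, the block sets different tumours beside a cerebellum number on each chip.

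An adjusted p below 0.01 left 1432 higher probe sets on 430A, 699 higher and 1069 lower on 430B, and 986 higher genes. A log2 fold change of at least 1 left 1002 higher and 1680 lower on 430A, 611 and 885 on 430B, and 752 and 1236 genes, by its construction. Scaling 430B on shared probe sets gave 700 higher and 2714 lower and put the median of all 430B probe sets at -0.25, against -0.02 as deposited. Called lists fell from 25 to 0 with an estimated correlation and to 0 in the matched order with one. The correlation between chips was 0.556 with pseudocount 64, 0.537 with no filter, 0.687 with the lowest 50% left out and 0.564 without the 430B arrays of tumours 1 and 2, and the cause was not tested. Chromosome medians outside the central range fell from 22 to 13. No named gene or list reversed. Of 160 named genes, the fold change moved by over 1.5 times in 81 with pseudocount 64, in 50 of 159 with pseudocount 1 (Top2a 3.08 and 5.24) in 23 with the mean over probe sets, and in 2 with no filter and 2 with the brightest probe set. Without 430B tumours 1 and 2 that chip had 1444 higher and 2432 lower probe sets, where a lone tumour is assumed to vary like the cerebellum samples.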

Other observations

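On each chip, most genes in which 1 tumour lay apart from both others set apart the same tumour. On 430A, tumour 2 lay more than 1 log2 unit above both others in 30 genes and below both in 28, against 1 and 2 for tumour 1 and 2 and 5 for tumour 3. The genes low in tumour 2 included Aqp4, a water channel of astrocytes (104 against 327 and 277 in tumours 1 and 3), Mbp (40.0 against 171 and 115), Ptgds (59.7 against 175 and 189) and Fabp7. Relative to the other tumours, the median of the myelinating oligodendrocyte markers was -0.05 in tumour 2 and -0.08 in tumour 3, so Mbp does not stand for its list, and in tumour 2 those of the Bergmann glia and astrocyte, oligodendrocyte precursor and MHC lists were -0.27, -0.57 and 0.56. The genes high in it included Pdlim3 (97.8 against 13.8 and 12.1), Sfrp2 (142 against 21.3 and 25.2), Cd74 (268 against 65.4 and 64.6) and Ccnd2 (1370 against 606 and 615). On 430B, tumour 3, which matches it in the shared probe sets, lay below both others in 92 genes and above in 5. Tumour 1 of 430B lay above both others in 9 genes and below in 1, and tumour 2 lay apart in none. The limit of 1 was chosen after the data were seen, since a limit of 2 tried first gave 0 genes on 430A and gives 2 on 430B. After quantile normalization, also chosen after the data were seen, 43 of the 92 still lay below, and 30 of the 30 higher and 26 of the 28 lower genes of 430A tumour 2 still lay apart. These genes were picked by size in single tumours and were not tested.

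Of the tests in the paragraphs that follow, the quantile-normalized comparison of tumour orders and the one on bright probe sets of 430B were set before their results were seen, and the others after.

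The mismatch of tumour numbers between the chips may come from numbers given in a different order for each chip. In genes measured by different probe sets, the matched order exceeded the order of the labels by 0.812 in mean r. Its mean r was 0.520, against 0.294 for the best of the other orders. Brightness of the 430B arrays would have to favour the order of the labels after quantile normalization, and the matched order was then ahead by 0.837. Which chip carries the numbers the animals had stays open, and no biological explanation was tested.

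Cerebellum 1 carried more of the genes that were high in tumours than cerebellum 2 did. Of 198 genes over 2 log2 units higher in tumours, 162 lay above in cerebellum 1, as Ccnd2 (105 against 21.3) and Insm1 (42.6 against 7.5), with a median log2 difference of 0.37 and a median implied share of tumour RNA of 4.37% (quartiles 1.32% and 7.41%). Array scaling is argued against, since genes that did not differ between tissues and were as bright in cerebellum had a median difference between the samples 0.360 lower. A single share of tumour RNA in the dissected tissue and precursor cells outside the tumour could both account for it, with 13.1% of the genes over 2 robust SD from the level of one share, or 8.59% when the level of any of the 3 tumours is allowed, against 6.58% of genes that did not differ, and precursor genes only 0.735 percentage points (SE over genes 1.89) above microglia genes in implied share, too close to separate them. The share alone would lower the 356 genes low in tumours by a median log2 of -0.05, and they were at -0.24, with 1 array on each side, so what else differs between the cerebellum samples stays open.

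The shared probe sets were brighter on the 430B arrays of tumours 1 and 2, by 0.79 and 0.76 log2 units over the 430A tumours, than on that of tumour 3, at 0.13, or of the cerebellum samples, at 0.10 and 0.20. One scaling factor per array is argued against, because it would move all brightness ranges alike, and other probe sets at log2 8 to 9 differed between these tumours and tumour 3 by 0.467 more than those at 5 to 6. The 430A array that matches tumour 3 lay at -0.0931 from the other 430A tumours in the shared probe sets. That value cannot decide on RNA quality. It speaks only on tumour 3, whereas tumours 1 and 2 were the arrays apart from the cerebellum samples. A fault of the 430B preparation alone would also not show on 430A. A difference that depends on brightness may be the source, as 1237 other probe sets in the brightness range of the shared ones were higher by 0.469, though less than the shared ones, at 0.65. Over bins of brightness the median of other probe sets went from -0.12 (log2 3 to 4) to 0.52 (8 to 9) and back to 0.23 (10 to 13), and its origin stays open.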
